A study of Mus musculus with 28 samples.

How the data were processed

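Bulk RNA sequencing was done on sorted mouse medullary thymic epithelial cells (mTECs), the thymic stromal cells that transcribe many genes of peripheral tissues. Per the labels' protocols, thymi were digested, cells carrying the blood-cell marker CD45 were depleted magnetically, and 1000 cells per library were sorted by flow cytometry, with a repeat sort where numbers allowed. RNA was reverse transcribed from an oligo(dT) primer, amplified, cut and tagged with Tn5 and amplified for 18 PCR cycles, then read as paired ends of 38 bases. The kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. There were no molecular identifiers, so reads are not independent molecules and the statistics treat PCR copies as counts.

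The deposited table holds read counts per gene, whole numbers that were not normalized, for 55011 gene symbols in 28 libraries. Per the submitters' processing notes the authors used STAR 2.7.3a, featureCounts and the mouse build mm10; the gene annotation and the counting settings are not given in the sources used here. All columns matched a sample's title, and 0 columns were left without a sample. Positions are from GENCODE M21 on the same build (GRCm38), in which 53009 of the symbols were found.

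Libraries were grouped by the labels into 8 groups of 3 or 4. The labels give a number to each thymus but do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Total counts were 4330120 to 8342583 per library, and 27045 to 31055 genes had at least 1 read. Over the 36 pairs of replicates, the chi-square of the counts per degree of freedom was 5.93 to 24.2, so no pair agreed within sampling noise. PCR copies raise this value too, so it does not show that the libraries came from separate samples. Every library was counted separately.

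Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization), after a filter on low counts by group (filterByExpr, minimum count 10, minimum total 15). P-values were adjusted by Benjamini-Hochberg over the genes tested and genes with adjusted p under 0.05 were called. Log2 fold changes are given with standard errors (SE), and values of named genes are CPM (counts scaled to a common library total) on TMM-scaled libraries with SD. Those of the targeted genes per group are CPM of the plain totals. The wild-type gates had a fit of their own with 6 libraries, the 4 mTEClo genotypes shared a fit of 14 libraries, the mTEChi genotypes a fit of 8, and comparisons across the sorted subsets a fit of 16. There were 11 comparisons. Groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

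The genes named in each comparison were Hnf4a, Hnf4g and Aire, then the 8 called genes with the largest fold in each direction (5 for interactions) with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, a condition dropped for interactions. Gene models without a proper symbol (Gm and Rik names) and pseudogene symbols were counted but not named. Then came the called members of smallest p in each list, up to 4 for brush border, lipid handling, transporters, plasma proteins, hepatocyte metabolism and transcription factors and up to 2 for the others. The text names a selection of these. For a gene at 0 in every library of a group the fold is given as a bound against 3 counts over the group, and no fold is given for a gene with 1 to 3 counts in a group.

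The 27 gene lists, with 571 genes, were textbook markers: enterocyte brush border, intestinal lipid handling, intestinal transporters, hepatocyte plasma proteins, hepatocyte metabolism, xenobiotic metabolism, gut and liver transcription factors, kidney proximal tubule; microfold, tuft, ciliated, neuroendocrine, keratinocyte, muscle, goblet and pancreatic acinar genes, which mark mTECs resembling those cells; Aire-stage mTEC, CCL21-type immature mTEC, cortical epithelium and proliferation; thymocyte, myeloid and dendritic, B cell, fibroblast and pericyte, endothelium and erythroid genes as markers of other cell types; and dissociation stress. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison; unless said otherwise a list's adjusted p is this one. Camera with an estimated correlation and fry were run beside it. The erythroid list had 2 measured genes in mTEClo and was not tested there. An entero-hepato signature was defined from the wild-type gates as genes called with a log2 fold change over 1, which gave 2147 higher and 2268 lower genes, and both sets were tested in the mutants, whose libraries had no part in choosing them. The signature without further words is the higher set.

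In simulated counts with 200 changed genes, the test recovered 76.1% of genes changed 2-fold in the comparison of mTEClo lacking both genes with control, 71.6% for removal of Hnf4a, 74.6% for removal of Hnf4g, 77.6% in mTEChi, 55.2% for the interaction with subset and 34.3% for the interaction of the genotypes. Each of these runs also made 4 to 12 false calls. The changed genes had a mean of at least 10 CPM, genes varied independently, and each gene's spread was set by the trend for its level. The shares therefore do not cover lower genes, genes that vary more than the trend or libraries whose genes vary together.

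Libraries share replicate numbers across groups. Whether equal numbers pair libraries was checked by the correlation of their deviations from the group means. For Hnf4a-removed against Hnf4g-removed mTEClo every same-number correlation was over 0.1 among the 9284 genes with a mean log2 CPM of at least 4 (0.12 to 0.36), but over all 21815 genes the lowest was 0.05. This comparison met the pairing rule on the smaller gene set alone. Its values are from the fit without a block, and blocked values are given where they end a call. For the others the number was taken as a number alone. Yet the leading principal component of the mTEClo deviations (27.4% of their variance) rose with the number in every genotype. It went from -12.6 to 12.4 in control, -14.7 to 10.8 in Hnf4a-removed, -31.3 to 19.3 in Hnf4g-removed and -6.05 to 4.25 in double-mutant cells. A factor shared by equal numbers stays open, and fits without a block do not account for it.

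Alternatives were median-of-ratios size factors (RLE), no filter, a minimum count of 50, DESeq2 1.42.0, limma voom with quality weights, libraries thinned to the smallest, the replicate number as a block, fits of 2 groups alone and leaving out each library in turn. After the data were seen, 3 of the 4 mTEClo libraries with the number 1 were also left out (control, Hnf4a-removed and Hnf4g-removed, but not double-mutant). These lay lowest on the leading component of the deviations, at -12.6, -14.7 and -31.3. The double-mutant library with that number, at -6.05, was the lowest of its own group and was kept. Where double-mutant mTEClo take part, results without the 3 libraries are therefore no balanced check. Also after the data were seen, the signature was tested for the interaction of the genotypes. Signatures of log2 fold change over 2 or of the 200 genes of smallest p were then tested with an estimated correlation. Other splits of the libraries into groups of the same sizes were counted, up to 100 per comparison. Reads of paralogs that share sequence, such as Serpina1b, Reg1, Lyz1, Ccl6 and Ccl9, Mt1 and Mt2 and the Tas2r genes, may be divided between copies by the counting, and their values are uncertain.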

Results

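The data were read counts per gene from 28 libraries of sorted mouse mTECs on a C57BL/6 background. In wild-type thymus, an entero-hepato gate (n = 3), which the title of the series links to gut and liver genes, was sorted beside a gate outside it (n = 3). In mice with the thymic epithelial driver Foxn1-Cre, post-Aire mTEClo were sorted from control (Hnf4a fl/+, Hnf4g +/-, n = 4), Hnf4a-removed (Hnf4a fl/fl, Hnf4g +/-, n = 3), Hnf4g-removed (Hnf4a fl/+, Hnf4g -/-, n = 3) and double-mutant thymus (Hnf4a fl/fl, Hnf4g -/-, n = 4). The subset mTEChi was sorted from control (n = 4) and double-mutant thymus (n = 4). The control mice thus carried 1 intact allele of each gene, not 2. Total counts per library were 5935616 to 6897484 in the entero-hepato gate, 4330120 to 4647944 outside it, 5504278 to 7599304 in mTEClo and 5344084 to 8342583 in mTEChi.

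The targeted genes, which encode the paralogous nuclear receptors HNF4A and HNF4G, were low in all mTEClo and mTEChi groups. Hnf4a (chromosome 2, 163506808 to 163572910) was at 4.67 ± 2.09 CPM (SD, n = 4) in control mTEClo, 3.38 ± 1.11 (n = 3) in Hnf4a-removed, 3.36 ± 0.869 (n = 3) in Hnf4g-removed and 3.15 ± 0.851 (n = 4) in double-mutant mTEClo, from 16 to 48 reads per library. In mTEChi it was at 4.64 ± 3.16 CPM (n = 4) in control and 4.26 ± 2.45 (n = 4) in double-mutant cells, from 7 to 65 reads. Hnf4g (chromosome 3, 3508030 to 3658052) was at 12.8 ± 2.71 CPM in control mTEClo, 7.76 ± 1.76 in Hnf4a-removed, 8.12 ± 0.689 in Hnf4g-removed and 5.23 ± 2.24 in double-mutant mTEClo, and at 20.6 ± 3.51 against 7.90 ± 3.90 in mTEChi. By edgeR with all libraries neither gene passed the test in a mutant comparison: in the double mutants the adjusted p of Hnf4g was 0.0633 in mTEClo and 0.0862 in mTEChi, and that of Hnf4a 0.645 and 0.964. Hnf4g passed as lower in double-mutant mTEClo without control replicate 1 (adjusted p = 0.0420) or double-mutant replicate 4 (0.0238), and in mTEChi without double-mutant replicate 4 (0.0127). It also passed by DESeq2 in both (0.00507 and 0.00271) and by voom in mTEClo (0.0305). The deleted part of each gene is not given in the sources used here, and counts over a whole gene can hold reads from outside it and, for Hnf4a, from the antisense gene Hnf4aos, so these counts do not check the genotype labels.

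Cells of the entero-hepato gate carried many genes of the gut at far higher levels than cells outside it. Lypd8, a secreted protein of the colon, was at 7484 ± 2023 CPM against 72.0 ± 19.7 (SD, n = 3 each; log2 fold change 6.70, SE 0.28, adjusted p = 1.13e-06 by edgeR). Guca2a, the gut hormone guanylin, was at 134 ± 40.2 CPM with a log2 fold change of 7.92 (SE 0.35), Ces2a at 565 against 2.77 and Clca4b at 143 against 1.12. Hnf4a was at 47.4 ± 16.5 against 5.55 ± 0.405 CPM (log2 fold change 3.09, SE 0.30, adjusted p = 6.43e-05) and Hnf4g at 140 ± 26.3 against 18.1 ± 1.61 (2.95, SE 0.17, adjusted p = 3.85e-06). Aire, the regulator of peripheral-tissue genes in mTECs, was lower at 835 ± 203 against 1571 ± 56.1 CPM (log2 fold change -0.91, SE 0.16, adjusted p = 0.00192).

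Of 16811 genes tested, 3822 were higher and 3657 lower in the entero-hepato gate (edgeR). Shares of the counts lay apart between the gates, with mitochondrial genes at 0.861% (SD 0.121, n = 3) in the gate against 1.59% (SD 0.267, n = 3) outside it, ribosomal protein genes at 0.940% against 2.33% and Gm10800 at 1.07% against 2.46% (exact permutation p = 0.1 each, the smallest that 3 against 3 libraries allow), and whether cell type or library quality makes these was not tested. Brush border genes rose as a list, with 22 of 27 measured members higher and 1 lower (23 and 1 adjusted over the list alone). The list's adjusted p was 6.8e-29 with the preset and 0.0641 with an estimated correlation. Among the members Cdh17 was at 1187 ± 113 against 53.8 ± 4.55 CPM, Cdhr5 at 1147 against 87.5, Muc13 at 1032 against 23.9 and Vil1, which encodes villin of the microvillus core, at 595 against 41.4. Genes of intestinal lipid handling (18 of 21 higher, 1 lower, 18 and 1 over the list alone) included the apolipoproteins Apoa4, at 953 against 28.6 CPM, and Apoc3, at 579 against 9.61 (adjusted p = 0.0834 with an estimated correlation). Intestinal transporters (20 of 23 higher, also over the list alone; p = 0.0834 with an estimated correlation) included the zinc importer Slc39a4, at 737 against 31.0 CPM, and Slc7a9, at 72.8 against 0.924. Xenobiotic metabolism genes (22 of 27 higher, 1 lower, 22 and 2 over the list alone; 0.0834 likewise) included Ces2e, at 892 against 8.85 CPM, and Fmo5, at 404 against 29.5. Of hepatocyte plasma proteins 13 of 32 were higher and 2 lower (the same numbers over the list alone), with complement C3 at 4728 against 799 CPM and Ambp at 56.9 against 7.01 (adjusted p = 0.00649, and 0.148 with an estimated correlation). Hepatocyte metabolism (7 of 27 higher, 6 over the list alone) did not pass as a list, with adjusted p = 0.0827; its called members included Pck1, at 284 against 13.5 CPM. Of gut and liver transcription factors 10 of 21 were higher and 1 lower, Vdr at 489 against 118 CPM and Gata4 at 23.1 against 3.22 (adjusted p = 0.00547, and 0.148 with an estimated correlation). The microfold list, 10 of 11 higher and 1 lower, passed with both correlations (3.71e-13 and 0.0382), with Ccl9 at 560 against 25.7 CPM and Pglyrp1 at 996 against 76.2.

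Proliferation genes fell in the entero-hepato gate in all 31 members of the list (adjusted p = 5.29e-33, and 0.0834 with an estimated correlation), Ccna2 from 82.2 to 1.37 CPM and Nusap1 from 47.7 to 3.31. Tuft genes (18 of 23 lower, 2 higher; 20 and 2 over the list alone) included the taste channel Trpm5, at 39.0 against 493 CPM, and Avil, at 39.9 against 460 (adjusted p = 1.03e-08, and 0.321 with an estimated correlation). Ciliated genes (17 of 21 lower, 20 over the list alone; 1.11e-05 and 0.321) included Rsph1, at 4.97 against 27.3 CPM. CCL21-type immature mTEC genes (8 of 10 lower, 1 higher; 4.81e-07 and 0.0641) included Krt5, at 106 against 1324 CPM, and Lifr, at 42.1 against 583. The goblet list (8 of 18 higher; 0.00305 and 0.0867) included Clca1 and Dmbt1. Of the Aire-stage list 12 of 17 were higher, H2-Ab1 at 17949 against 7537 CPM among them, and 2 were lower, Aire and Ciita (0.000446 and 0.252). The lists for kidney proximal tubule (4 of 12 higher, adjusted p = 0.104), keratinocyte (7 of 25 higher, 0.107), pancreatic acinar (4 of 15 higher and 1 lower, 0.398), neuroendocrine (3 of 23 higher and 4 lower, 0.88), muscle (4 of 21 higher and 2 lower, 0.767), cortical epithelium (4 of 11 higher and 3 lower, 0.656) and dissociation stress (4 of 17 higher and 8 lower, 0.363) did not pass. Among markers of other cell types, the erythroid list was higher in the same libraries (5 of 6 genes; 0.000674, and 0.0941 with an estimated correlation), with Hbb-bs at 103 against 0.665 CPM, and so was the myeloid list (6 of 15; 0.0152 and 0.246), with Ctss at 452 against 173 CPM. The thymocyte (2 of 16 higher, 0.568), B cell (2 of 10 higher and 2 lower, 0.839), fibroblast and pericyte (1 higher and 1 lower of 13, 0.755) and endothelium lists (6 of 13 higher and 1 lower, 0.409) did not pass. With 3 libraries against 3 there are 10 splits, so the grouping itself cannot reach a share under 0.1.

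Post-Aire mTEClo lacking both Hnf4 genes had lower levels of enterocyte genes than control mTEClo. Fabp1, an intracellular lipid carrier of gut and liver, was at 3.12 ± 0.547 CPM against 28.4 ± 14.1 (SD, n = 4 each; log2 fold change -3.18, SE 0.35, adjusted p = 0.0007 by edgeR). Mep1a, a brush border protease, was at 7.84 ± 5.29 against 64.6 ± 18.8 CPM, Muc13 at 15.2 ± 5.46 against 60.1 and Vil1 at 33.4 ± 4.06 against 79.3 ± 21.2. The chemokine gene Ccl6 was at 7.17 ± 2.42 against 85.1 ± 31.4 CPM and Ccl9 at 44.6 ± 7.80 against 151 ± 24.8. Serinc3 (chromosome 2, 163623272 to 163645131) was higher at 320 ± 21.5 against 168 ± 11.7 CPM (log2 fold change 0.93, SE 0.09, adjusted p = 0.000311).

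Of 18775 genes tested, 30 were higher and 109 lower. Brush border genes fell as a list, 7 of 25 members lower (10 over the list alone; mean log2 fold change -0.88), and this list passed with both correlations (1.47e-13 and 0.00419). The microfold list (4 of 11 lower, 7 over the list alone; 1.33e-12 and 0.0195) and xenobiotic metabolism (1 of 25 lower, 6 over the list alone; 5.96e-06 and 0.0195), with Cyp3a13 at 17.3 against 39.6 CPM, passed with both as well. Lipid handling (4 of 21 lower, 5 over the list alone; 8.27e-05, and 0.139 with an estimated correlation) included Apoa4, at 1.95 against 29.3 CPM, Apoc3, at 0.660 against 15.7, and the sterol exporter Abcg5, at 2.22 against 9.82. Hepatocyte plasma proteins (3 of 34 lower, 5 over the list alone; 0.00797 and 0.139) included Ttr, at 0.348 against 11.1 CPM, F10, at 0.785 against 6.95, and Serpina1b, at 0.173 against 5.68. The neuroendocrine list had 0 of 25 members called by edgeR over all genes and 4 lower over the list alone (1.29e-06, and 0.0761 with an estimated correlation). The tuft list was higher, 2 of 23 members over all genes and 14 over the list alone (4.31e-16, and 0.0761 with an estimated correlation), with Avil at 3433 ± 175 against 2584 ± 349 CPM and the prostaglandin synthase Ptgs1 at 688 ± 27.0 against 444 ± 72.3. Intestinal transporters (1 of 22 higher, adjusted p = 0.154) and gut and liver transcription factors (0.505) did not pass. Hepatocyte metabolism (0 of 23 called by edgeR; 0.000742, and 0.133 with an estimated correlation) and cortical epithelium (3 of 11 lower over the list alone; 0.00681 and 0.148) were lower with the preset correlation alone, as were ciliated genes (0.0324 and 0.585). Dissociation stress genes were higher (0.0226 and 0.464). The Aire-stage list (11 of 17 lower over the list alone, 1.42e-09) and the proliferation list (6 of 31, 1.59e-10) fell in the same libraries with the preset correlation but not with an estimated one (0.19 and 0.139), and Aire was at 192 ± 36.7 against 405 ± 146 CPM (adjusted p = 0.242, and 0.000496 without the libraries left out after the data were seen). That omission drops control replicate 1, which had the lowest Aire of the controls (207 CPM of the plain totals), and so by itself raises control Aire. The fibroblast and myeloid lists also fell (0.0226 and 0.00797, and 0.139 and 0.32 with an estimated correlation).

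The entero-hepato signature fell in these cells. Its 2020 measured genes had a mean log2 fold change of -0.43, 70.3% of them were negative, and 89 of the 108 genes called lower that both fits had tested belonged to it, against 13.4 by chance (Fisher's exact test, one count per gene, genes not being independent, p = 2.74e-62). Camera gave p = 1.87e-13 with the preset and 0.00181 with an estimated correlation. The mean was -0.81 for signature genes with a log2 fold change over 2 between the gates and -0.92 for the 200 of smallest p (camera p = 0.000301 and 0.000488 with an estimated correlation), called the narrower signatures below. The number of called genes depended on single libraries: it was 89, 57 and 60 without control replicates 2, 3 and 4, 55, 47 and 53 without double-mutant replicates 1, 2 and 3, and 543 without the 3 libraries left out after the data were seen. Of 29 called genes that the naming rule gave, 10 kept their call whichever library was left out, Fabp1, Mep1a, Muc13, Vil1, Ccl6, Ccl9 and Serinc3 among them. Apoa4 and Apoc3 lost their calls without control replicate 3 or 4 or any double-mutant replicate, Abcg5 and Avil without any of those or control replicate 2, while Ttr did so without control replicate 3 or 4 or double-mutant replicate 2, 3 or 4. F10 lost its call without control replicate 2 or 4 or any double-mutant replicate, Cyp3a13 without any control replicate or double-mutant replicate 1 or 3, and Ptgs1 without control replicate 3 or double-mutant replicate 2. DESeq2 called 456 genes, the fit on these 2 groups 295 and the test without a filter 967.

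**Figure D1:**
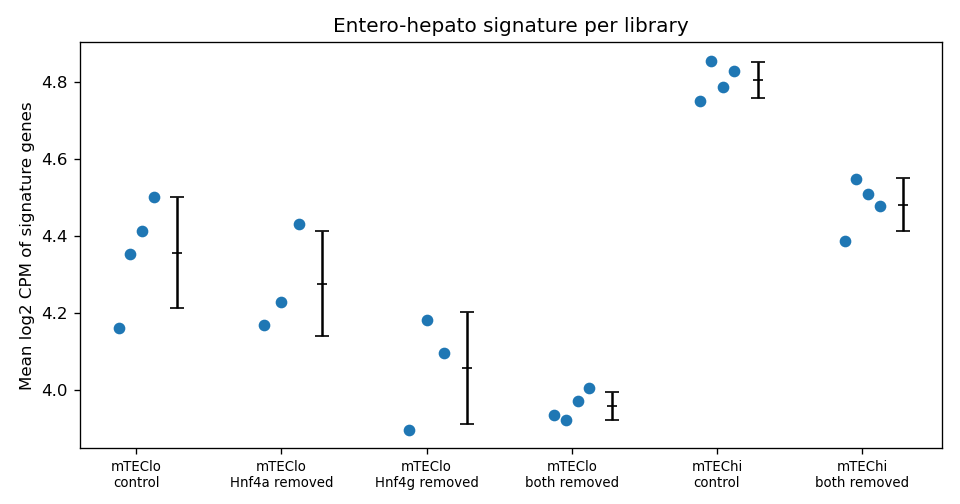
Mean log2 CPM of the signature genes (vertical axis) in each mTEClo and mTEChi library (points) by group, with the group mean and SD beside the points. The subsets come from separate fits, with 2020 signature genes in mTEClo and 2057 in mTEChi, so levels are not comparable between subsets. The 4 double-mutant mTEClo libraries lie below the 4 control mTEClo libraries, and the 4 double-mutant mTEChi libraries below the 4 control mTEChi libraries.

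Removal of Hnf4a with 1 Hnf4g allele kept gave 1 called gene in mTEClo. Serinc3 was at 288 ± 29.7 CPM (n = 3) against 168 ± 11.7 (n = 4; log2 fold change 0.78, SE 0.10, adjusted p = 0.00972 by edgeR). Fabp1, Mep1a and the other gut genes were not called, 0 genes were called lower, and 1130 genes had an unadjusted p under 0.05; DESeq2 called 8 genes and voom 1. The signature had a mean log2 fold change of -0.095 (camera p = 0.177, and 0.444 with an estimated correlation). It was -0.15, -0.062 and -0.029 without control replicates 1, 3 and 4 and -0.22 without Hnf4a-removed replicate 3, and passed without control replicate 1 or Hnf4a-removed replicate 3. The narrower signatures, at -0.17 and -0.15, passed with the preset correlation (camera p = 0.00677 and 0.0160) but not with an estimated one (0.231 and 0.417). The tuft list (higher, 1.68e-06), the goblet list (lower, 0.00103) and the dissociation stress list (higher, 0.00149) passed with the preset correlation and none of them with an estimated one (adjusted p = 0.7 each). Serinc3 lost its call in 5 of the 7 fits that left out a library (control replicates 1, 2 and 4 and Hnf4a-removed replicates 1 and 2, each with 0 genes called). It also lost its call in the fit on these 2 groups, with the replicate number as a block and without the libraries left out after the data were seen. Its log2 fold change stayed between 0.73 and 0.86 in the fits that left out a library.

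Removal of Hnf4g with 1 Hnf4a allele kept lowered a small set of gut genes in mTEClo. Fabp1 was at 3.00 ± 0.351 CPM (n = 3) against 28.4 ± 14.1 (n = 4; log2 fold change -3.24, SE 0.40, adjusted p = 0.00499 by edgeR). Trim31 was at 0.273 ± 0.0846 against 12.2 ± 4.60 CPM, Lyz1, a lysozyme of Paneth cells, at 40.5 ± 18.7 against 368 ± 164, Muc13 at 14.9 ± 6.51 against 60.1, Ccl6 at 10.2 ± 7.86 against 85.1 ± 31.4 and Clca4a at 2.90 against 22.1. Of 18775 genes, 0 were higher and 18 lower, with 1538 at an unadjusted p under 0.05, 143 called by DESeq2, 11 by voom and 11 without the libraries left out after the data were seen. The brush border list fell with both correlations (3 of 25 lower, 7 over the list alone, Cdhr5 and Vil1 among them; 1.17e-09 and 0.0113). The microfold list (2.42e-09), lipid handling (0.00113) and xenobiotic metabolism (0.000752) fell with the preset correlation and gave 0.0563, 0.344 and 0.0563 with an estimated one. The neuroendocrine (0.000583), ciliated, keratinocyte and cortical epithelium lists (0.0119 each) were lower and the dissociation stress list (0.0119) higher with the preset correlation. With an estimated one they gave 0.29, 0.563, 0.551, 0.332 and 0.551. The signature had a mean log2 fold change of -0.32 (camera p = 1.18e-11, and 0.00261 with an estimated correlation), and 17 of the 18 lower genes belonged to it. The narrower signatures were at -0.63 and -0.71. Of the 35 splits of these libraries 2 moved the signature as far, a share over 0.05. The count was 9, 9 and 10 without control replicates 2, 3 and 4 and 11 without Hnf4g-removed replicate 1. Fabp1, Trim31, Lyz1 and Ccl9 kept their calls whichever library was left out. Cdhr5 lost its call without any of the 7, Clca4a without all but control replicate 4, Vil1 without all but control replicate 1, Muc13 without all but Hnf4g-removed replicate 2, and Ccl6 without control replicate 3 or 4 or Hnf4g-removed replicate 2.

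Against Hnf4a-removed mTEClo, double-mutant mTEClo had lower Mep1a, at 7.84 ± 5.29 CPM (n = 4) against 64.3 ± 13.3 (n = 3; log2 fold change -3.04, SE 0.45, adjusted p = 0.0113 by edgeR). Ccl6 was at 7.17 against 80.8 CPM, Lyz1 at 35.6 against 292, Ceacam20 at 1.00 against 12.5, Lypd8 at 12.9 against 100 and Fabp1 at 3.12 against 18.8, while the secretory protein gene Scgb1a1 was higher at 204 ± 20.4 against 77.8 ± 30.6 CPM. There were 6 genes higher and 49 lower. The brush border list (3 of 25 lower, 10 over the list alone; 2.74e-10 and 0.00824) and the microfold list (5 of 11 lower, 8 over the list alone; 3.22e-17 and 0.00888) fell with both correlations, and the signature had a mean log2 fold change of -0.34 (camera p = 9.38e-10, and 0.00546 with an estimated correlation), or -0.22 without Hnf4a-removed replicate 3 and -0.64 and -0.76 for the narrower signatures. With the preset correlation alone lipid handling (0.00175), xenobiotic metabolism (0.00157), neuroendocrine (0.00175), Aire-stage (5.23e-06), proliferation (4.5e-08) and fibroblast genes (0.0303) were lower, and tuft (0.000575) and goblet genes (0.00175) higher. With an estimated correlation these gave 0.323, 0.101, 0.265, 0.4, 0.265, 0.262, 0.463 and 0.262. The count was 34 and 7 without Hnf4a-removed replicates 2 and 3, 25, 18 and 31 without double-mutant replicates 1, 3 and 4, 278 by DESeq2, 34 by voom and 216 without the libraries left out after the data were seen. Ccl6, Ccl9, Fabp1 and Lyz1 kept their calls whichever library was left out, Mep1a, Ceacam20 and Lypd8 lost theirs without Hnf4a-removed replicate 3, and Scgb1a1 without any of the 7.

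Against Hnf4g-removed mTEClo, double-mutant mTEClo differed in 2 genes. Serinc3 was higher at 320 ± 21.5 CPM (n = 4) against 157 ± 10.5 (n = 3; log2 fold change 1.02, SE 0.10, adjusted p = 0.000401 by edgeR), and the ribosomal protein gene Rps12 lower at 45.5 ± 4.69 against 108 ± 25.9 (-1.24, SE 0.17, adjusted p = 0.0134). The signature had a mean log2 fold change of -0.12 (camera p = 0.326, and 0.576 with an estimated correlation), or -0.012 and -0.070 without Hnf4g-removed replicates 2 and 3. The narrower signatures, at -0.18 and -0.21, passed with the preset correlation (camera p = 0.0168 and 0.0143) but not with an estimated one (0.287 and 0.407). Tuft genes were higher (10 of 23 over the list alone; 1.03e-10) and proliferation (7 of 31 lower over the list alone; 1.85e-09) and Aire-stage genes (4 of 17; 3.02e-07) lower with the preset correlation, and with an estimated one these gave 0.489, 0.489 and 0.667. The count was 119 without Hnf4g-removed replicate 1, 9 without double-mutant replicate 2, 1 without Hnf4g-removed replicate 2 or without double-mutant replicates 1, 3 or 4, 197 by DESeq2, 39 by voom, 1 in the fit on these 2 groups and 255 without the libraries left out after the data were seen, so the low count does not show that the groups were alike. Rps12 lost its call without Hnf4g-removed replicate 2 or double-mutant replicate 1, 3 or 4, and Serinc3 kept its call without each library in turn.

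Hnf4a-removed and Hnf4g-removed mTEClo differed directly in gut genes. Trim31 was at 11.3 ± 2.09 CPM where Hnf4a was removed against 0.273 ± 0.0846 where Hnf4g was removed (n = 3 each; log2 fold change 5.28, SE 0.70, adjusted p = 0.0106 by edgeR), Fabp1 at 18.8 ± 3.62 against 3.00 ± 0.351, Lyz1 at 292 against 40.5 and Ccl9 at 151 against 44.7. Serinc3, chosen after its values were seen, was also higher (log2 fold change 0.87, SE 0.10) and Slc25a37, a mitochondrial iron importer, lower at 27.5 against 52.5 CPM. In all 11 genes were higher and 1 lower, against 1 gene called in the fit on these 2 groups alone, 6 by voom, 98 by DESeq2 and 7 without the libraries left out after the data were seen. The brush border list (1.07e-06 and 0.0204) and the microfold list (2.54e-13 and 0.0204) were higher with both correlations, and the signature had a mean log2 fold change of 0.22 (camera p = 9.08e-08, and 0.0104 with an estimated correlation), or 0.11 without Hnf4a-removed replicate 3 and 0.34 without Hnf4g-removed replicate 2. The narrower signatures were at 0.46 and 0.55. Lipid handling (0.0326, and 0.754 with an estimated correlation) and tuft genes (0.0248 and 0.755) were also higher and goblet genes (0.000202 and 0.182) lower. With the replicate number as a block 17 genes were called, 10 of them shared, and Ccl6 (adjusted p = 0.06) and Rhoc (0.0658) lost their calls. Trim31 (adjusted p = 0.0257 by edgeR with the block) and Fabp1 (0.0442) kept theirs. All other values of this comparison are without a block. The count was 39 without Hnf4g-removed replicate 3 and 2 without Hnf4a-removed replicate 3. Trim31 kept its call whichever library was left out. Fabp1 lost its call without Hnf4a-removed replicate 1 or 3 or Hnf4g-removed replicate 1 or 2, Lyz1 without Hnf4a-removed replicate 2 or 3 or Hnf4g-removed replicate 1 or 2, Slc25a37 without Hnf4a-removed replicate 2 or 3, and Ccl9 without Hnf4a-removed replicate 3. Ccl6 lost its call without Hnf4a-removed replicate 1 or 3 or Hnf4g-removed replicate 2, and Rhoc without any of the 6.

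The interaction of the genotypes asks whether removing both genes differed from the sum of removing each. EdgeR called 0 genes, with 1473 at an unadjusted p under 0.05, against 100 by DESeq2 and 0 by voom. It called 14 without the libraries left out after the data were seen, and 2, 1 and 8 without Hnf4g-removed replicate 3, Hnf4a-removed replicate 1 and double-mutant replicate 2. The signature's mean log2 fold change was -0.024, while camera had the direction up (p = 0.918, and 0.953 with an estimated correlation), and it ranged from -0.083 without control replicate 4 to 0.097 without Hnf4a-removed replicate 3, with -0.011 and -0.058 for the narrower signatures. Proliferation (0.000421) and Aire-stage genes (0.0183) were lower with the preset correlation and gave 0.98 each with an estimated one.

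In mTEChi, the subset that holds Aire-expressing cells, removal of both genes also lowered gut and liver genes. Muc13 was at 15.9 ± 1.64 CPM against 79.6 ± 13.8 (n = 4 each; log2 fold change -2.33, SE 0.16, adjusted p = 2.91e-05 by edgeR), Clrn3 at 2.14 ± 2.09 against 61.9 ± 4.71, Vil1 at 18.7 ± 3.29 against 66.9 ± 10.9 and Cdhr5 at 44.2 ± 11.4 against 164 ± 22.3. Among genes of the liver, Fgg, a fibrinogen chain, was at 16.5 ± 7.07 against 78.4 ± 26.3 CPM and Ttr, the thyroxine carrier, at 2.34 against 32.2. C3 was at 390 against 758 and Pck1, an enzyme of gluconeogenesis, at 12.6 against 50.2. Higher genes included the metallothionein genes Mt1, at 430 ± 64.1 against 213 ± 15.8 CPM, and Mt2, Pir, Crnn, Gnat3 and Serinc3, at 217 ± 19.0 against 142 ± 13.8. Aire was at 1956 ± 420 against 1754 ± 384 CPM (adjusted p = 0.798).

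Of 18413 genes, 7 were higher and 110 lower. Lists that fell with both correlations were brush border (6 of 25 lower, 7 over the list alone; 1.1e-23 and 0.00529), lipid handling (5 of 20, 9 over the list alone; 2.28e-14 and 0.00529), with Apoc3 at 4.79 against 35.6 CPM and Fabp1 at 6.68 against 25.7, intestinal transporters (1 of 22, 4 over the list alone; 3.49e-05 and 0.0378), with Slc39a4 at 21.2 against 77.2 CPM, hepatocyte plasma proteins (5 of 33, 6 over the list alone; 1.36e-08 and 0.00652), xenobiotic metabolism (1 of 26, 6 over the list alone; 0.00177 and 0.049) and microfold genes (1 of 11, 6 over the list alone; 2.83e-09 and 0.0238). Hepatocyte metabolism (0.0316 and 0.279) and neuroendocrine genes (0.0429 and 0.274) were lower with the preset correlation alone, and the tuft list, with Gnat3 called, was higher (0.00588 and 0.434). Ciliated (2.18e-05), keratinocyte (3.49e-05), dissociation stress (0.00177) and proliferation genes (0.0279) were higher with the preset correlation and gave 0.279, 0.274, 0.406 and 0.694 with an estimated one. The signature had a mean log2 fold change of -0.32 over 2057 genes (camera p = 2.62e-21, and 0.000335 with an estimated correlation), and 95 of the 108 lower genes tested in both belonged to it, against 13.7 by chance. The narrower signatures were at -0.56 and -0.77. The count was 74 and 71 without control replicates 3 and 4, 188 without double-mutant replicate 3 and 439 by DESeq2. Of 27 called genes that the naming rule gave, 19 kept their call whichever library was left out. Serinc3 lost its call without control replicate 2, 3 or 4 or double-mutant replicate 1 or 4. Ttr lost its call without control replicate 2, 3 or 4 or double-mutant replicate 4, and Gnat3 without control replicate 1, 2 or 3 or double-mutant replicate 4.

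Of the genes tested in both subsets, 108 were lower in double-mutant mTEClo and 106 in double-mutant mTEChi, and 42 were lower in both, against 0.673 for independent lists (Fisher's exact test over genes, p = 2.58e-67). These include Apoc3, Ccl6, Clrn3, Fabp1, Mep1a, Muc13, Ttr and Vil1. Serinc3 was the 1 gene higher in both. The subsets have separate control libraries.

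**Figure D2:**
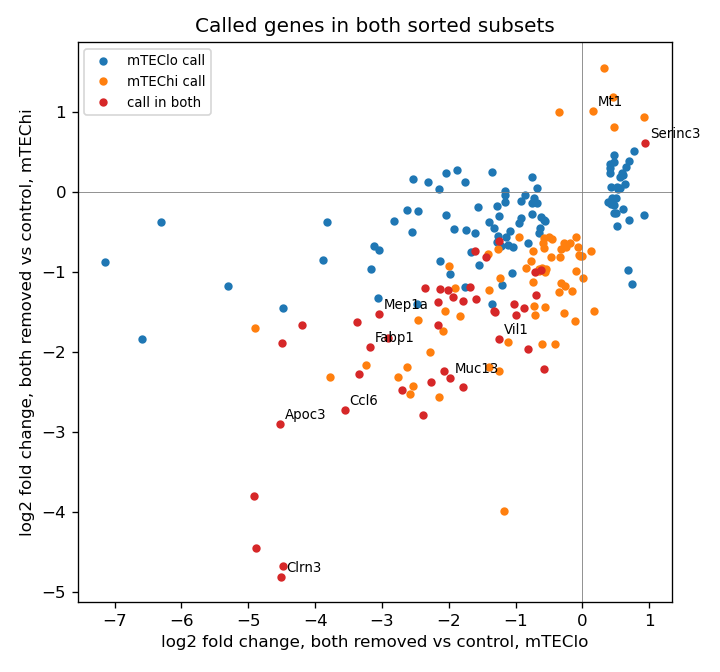
Log2 fold change in double-mutant against control mTEClo (horizontal axis) and mTEChi (vertical axis) of genes called in either subset, each point a gene, coloured by the subset in which it was called. The 42 genes lower in both lie in the lower left, with Serinc3 in the upper right.

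The mutant effect differed between the subsets in 12 genes by the test of the interaction. Cdhr5 fell more in mTEChi (interaction log2 fold change -1.50, SE 0.21, adjusted p = 0.0167 by edgeR) and so did F11r, a junction protein gene, at 419 ± 36.6 CPM in double-mutant against 730 ± 42.5 in control mTEChi (n = 4 each). Apoa4 fell more in mTEClo (3.03, SE 0.50, adjusted p = 0.0323). The signature's mean log2 fold change for the difference was 0.12, while camera had the direction down (p = 0.4, and 0.616 with an estimated correlation) and fry up. That mean was 0.039 without control mTEClo replicate 4 and 0.26 and 0.13 for the narrower signatures. Proliferation (1 of 31 higher, 16 over the list alone; 2.77e-13, and 0.254 with an estimated correlation) and Aire-stage genes (1 of 17, 9 over the list alone; 3.69e-13 and 0.204) were higher in mTEChi relative to mTEClo. So were ciliated (8.58e-06), keratinocyte (0.0023), cortical epithelium (0.00835), neuroendocrine (0.0165) and myeloid genes (0.041), with 0.389, 0.39, 0.204, 0.39 and 0.389 by an estimated correlation. The count was 85, 5 and 2 without control mTEClo replicates 1, 3 and 4, 2, 7 and 6 without double-mutant mTEClo replicates 1, 2 and 4, 3, 3, 6 and 1 without control mTEChi replicates 1, 2, 3 and 4, 5 and 157 without double-mutant mTEChi replicates 1 and 3, and 360 by DESeq2. F11r kept its call whichever library was left out. Cdhr5 lost its call without control mTEChi replicate 4, and Apoa4 without control mTEClo replicate 3 or 4, double-mutant mTEClo replicate 1, 2 or 4, any control mTEChi replicate or double-mutant mTEChi replicate 1.

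Control mTEChi and mTEClo differed in 8621 genes, 4496 higher and 4125 lower in mTEChi. The subsets were registered as separate runs of samples, so any difference in batch cannot be told apart from the subset in this comparison. Aire was at 1738 ± 379 CPM against 410 ± 148 (n = 4 each; log2 fold change 2.08, SE 0.25, adjusted p = 2.91e-06 by edgeR), and all 17 genes of the Aire-stage list were higher (7.43e-32, and 0.00591 with an estimated correlation), H2-Oa at 563 against 116 CPM. All 23 tuft genes were lower (3.01e-84 and 0.000243), with Gnat3 at 19.8 ± 3.22 against 581 ± 105 CPM, Alox5ap at 24.7 against 696 and the taste receptor Tas2r105 at 1.75 against 104. Hepatocyte plasma proteins (19 of 37 higher, 3 lower; 0.00424 and 0.0183) included Fga, at 26.3 against 0.357 CPM, and Serpinc1, at 78.1 against 13.3. Hepatocyte metabolism genes were higher too (19 of 31, with 2 lower; 0.00524, and 0.0589 with an estimated correlation). Proliferation genes were higher (29 of 31; 8.76e-11 and 0.12), Cenpe at 34.1 against 5.63 CPM. Dissociation stress genes were lower (13 of 17; 1.07e-06 and 0.12), Fos at 214 against 1075 CPM. Among markers of other cell types the myeloid list was higher in the same libraries (16 of 19; 5.11e-06 and 0.0119), Ctss at 450 against 143 CPM. The fibroblast and pericyte list was higher as well (8 of 13; 0.0022 and 0.061), Dcn at 95.8 against 7.83. The lipid handling list (13 of 21 higher and 2 lower; 0.0472 and 0.297) and cortical epithelium (7 of 11 higher and 1 lower; 0.00239 and 0.02) were higher, and the ciliated (13 of 22 lower and 4 higher; 0.0434 and 0.425) and keratinocyte lists (12 of 27 lower and 5 higher; 0.0193 and 0.38) lower. The chemokine gene Ccl12 and Cd300ld had 0 counts in all 4 control mTEClo libraries and were at least 107-fold and at least 108-fold higher in mTEChi, against 3 counts over the group. The bound for Ccl12 was 51-fold without control mTEChi replicate 1. Hnf4a (4.62 against 4.72 CPM, adjusted p = 0.978) and Hnf4g (20.5 against 12.9, adjusted p = 0.0968) did not pass.

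Comparisons against the same control mTEClo share chance values. Of the 109 genes lower in double-mutant and the 18 lower in Hnf4g-removed mTEClo, 14 were the same, against 0.105 for independent lists. Unchanged simulated groups shared 0, but edgeR called at most 1 lower gene in any of them, so that number does not show what shared controls add to an overlap. With the 4 controls split between the comparisons the overlap was 0 to 3, mean 1.67. Each of these fits had fewer controls, which by itself can end calls. Without control replicate 2 alone, Hnf4g removal had 9 called genes. The smaller overlap therefore does not show what shared controls add either. The covariance of all fold changes was 0.196 against 0.125 simulated, and 0.0824 with split controls. For double-mutant and Hnf4a-removed mTEClo the covariance was 0.160 against 0.125 simulated and 0.0313 with split controls, and for the separate removals of Hnf4a and Hnf4g 0.137 against 0.126 and 0.0298. The correlation of the fold changes over genes, which are not independent replicates, was 0.50 against 0.46 simulated for the first of these pairs, and lay below the simulated value for the others (0.42 against 0.46, and 0.39 against 0.42).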

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

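The tests of repression of Serinc3 in trans, of an effect in cis on Serinc3, of library depth and of cell composition with separate control libraries were chosen only after the results they bear on were seen.

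Serinc3 was higher in all comparisons that remove both functional Hnf4a alleles against a group that keeps 1, and the gene lies close to Hnf4a on chromosome 2. A change shared by the whole region is argued against: the 29 other tested genes within 1 Mb of Hnf4a had a median log2 fold change of -0.051 in double-mutant mTEClo (SE of their mean 0.125), against 0.93 for Serinc3. Pkig, the gene next to Serinc3, chosen after its values were seen, was lower by edgeR in double-mutant mTEChi (log2 fold change -0.94, adjusted p = 0.031) and was at -0.84 in double-mutant mTEClo (0.0824), -0.80 for Hnf4a removal (0.706) and -0.25 for Hnf4g removal (0.852). An effect in cis of the altered Hnf4a allele on Serinc3, which was at -0.091 where Hnf4g was removed, may or may not be on Serinc3 alone, and a variant linked to the floxed allele stays open. Repression of Serinc3 by HNF4 proteins cannot be told apart from it, because the gate with more Hnf4a and Hnf4g also had more Serinc3 (log2 fold change 1.37) but differs in cell type.

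The fall of the entero-hepato signature in double-mutant mTEClo could come from fewer Aire-stage cells in the sorted gate. The Aire-stage and proliferation lists were lower in the same libraries with the preset correlation, though not with an estimated one. As the whole cause this is argued against, as far as the difference between control mTEChi and mTEClo stands for Aire-stage cells. The 759 signature genes with an absolute log2 fold change under 0.5 in that difference still had a mean of -0.26 in double-mutant mTEClo (camera p = 0.00447 with an estimated correlation). In simulated unchanged groups with the same shared controls it was -0.025. The simulation drew genes independently and without a change in cell mix, so it does not give the value that fewer Aire-stage cells would. With 2 of the controls choosing such genes and the other two giving the fold change, the mean over the 6 splits was -0.20 (-0.22 to -0.18, camera p at most 0.0153 with an estimated correlation). Library depth is argued against as well, since with all libraries thinned to equal totals the mean was -0.44. A partial share of Aire-stage cells stays open, as do a loss of the entero-hepato mTECs themselves, which these tests do not address, and the removal of the Hnf4 genes, the biological difference that the design names.

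Other splits of the libraries were compared with the real grouping by the number of genes called. The grouping of double-mutant and control mTEClo was 1 of 35 splits to call as many genes (139, highest other 0). That for Hnf4g removal was 1 of 35 (18, highest other 1). That of double-mutant against Hnf4a-removed mTEClo was 1 of 35 (55, highest other 2). That of double-mutant and control mTEChi was 1 of 35 (117, highest other 1). That of control mTEChi and mTEClo was 1 of 35 (8621, highest other 1). In these 5 the real grouping called more genes than any other split, which argues against chance. It does not exclude chance, because 1 in 35 is the smallest share these splits allow and was not adjusted over the comparisons. Chance stays open for Hnf4a removal (2 of 35 splits, 1 gene, highest other 1). It does so for double-mutant against Hnf4g-removed mTEClo as well (2 of 35, 2 genes, highest other 3). For the interaction of the genotypes the real grouping called 0 genes, which every split equals, so the count decides nothing (100 of 100, highest other 1). The wild-type gates (1 of 10 splits, 7479 genes, highest other 0) and Hnf4a-removed against Hnf4g-removed mTEClo (1 of 10, 12 genes, highest other 6) have too few splits for a share under 0.05. In the latter, which met the pairing rule on the smaller gene set, the other splits that part all 3 same-number pairs called 0 genes by edgeR without a block. For the interaction with subset 3 of 100 splits called as many genes as the real 12, and the highest other called 545. It is the real grouping with the genotypes exchanged in mTEChi alone, so it holds the sum of both genotype effects. Splits for an interaction mix in such effects, are no reference without change and do not decide.

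The size of the signature's mean log2 fold change was compared in the same way. The real grouping ranked first in double-mutant against control mTEClo (1 of 35 splits, 0.435, highest other 0.349). It did so in mTEChi too (1 of 35, 0.322, highest other 0.218). It also ranked first, narrowly, in double-mutant against Hnf4a-removed mTEClo (1 of 35, 0.340, highest other 0.335). That mean was -0.22 without Hnf4a-removed replicate 3. A share of 1 in 35 is the smallest these splits allow and was not adjusted over the comparisons. It makes chance less likely there but does not exclude it. Chance stays open for Hnf4a removal (15 of 35, 0.0951, highest other 0.256) and Hnf4g removal (2 of 35, 0.316, highest other 0.329). It does so for double-mutant against Hnf4g-removed mTEClo as well (11 of 35, 0.119, highest other 0.175). For the interaction of the genotypes (94 of 100, 0.0240, highest other 0.612) and that with subset (60 of 100, 0.119, highest other 0.780) the splits mix in genotype effects and do not decide. Hnf4a-removed against Hnf4g-removed mTEClo (1 of 10, 0.221, highest other 0.216) has too few splits.

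A library stood far from the rest of its group in 3 of 40 tests, of which chance gives about 1 in 20. Control mTEClo replicate 1 had 1.49% of its counts in ribosomal protein genes, with the nearest replicate at 1.58%. Double-mutant mTEClo replicate 1 had 1.06% in Gm10800, with the nearest at 0.762%, and double-mutant mTEChi replicate 1 had 0.355%, with the nearest at 0.468%.

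The mutant effect differed between mTEChi and mTEClo by the interaction in 12 genes, given as log2 fold changes of the difference. It was higher in mTEChi for Apoa4 (3.03), Birc5 (2.07), H2-Eb1 (0.87), Reg1 (5.92), Slc30a2 (1.17), Trem2 (6.30), Vim (1.86) and Zfp423 (2.69), and lower for Cdhr5 (-1.50), F11r (-0.80), Myo15b (-1.63) and Pstpip2 (-0.76). Of the 10 genes among these that the naming rule gave, F11r kept its call whichever library was left out, and the others each lost theirs without control mTEChi replicate 4. Slc30a2 and Trem2 fall outside the naming rule and were chosen after their values were seen. Trem2 had 72 counts over control mTEClo and 0 over double-mutant mTEClo, at least 24.9-fold lower against 3 counts over the group, and its fitted value depends on the prior count and is no bound.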

How the results depend on the processing

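Leaving out 3 of the 4 mTEClo libraries with number 1, the double-mutant one being kept, was chosen after the data were seen. So were the signature's test for the interaction of the genotypes and the narrower signatures with an estimated correlation, while the other alternatives were not. The cause of a change was not tested except where fewer libraries or another set of tested genes make it. Gene counts are given in the order: double-mutant against control mTEClo, Hnf4a removal, Hnf4g removal, double-mutant against Hnf4a-removed, against Hnf4g-removed, Hnf4a-removed against Hnf4g-removed, interaction of the genotypes, double-mutant mTEChi, interaction with subset. With no filter they were 967, 212, 482, 733, 516, 404, 331, 619 and 321, and with DESeq2 456, 8, 143, 278, 197, 98, 100, 439 and 360. Without the 3 libraries the mTEClo comparisons had 543, 0, 11, 216, 255, 7 and 14, and the last, which loses 1 library, 85. Where double-mutant mTEClo take part, their own library with number 1 was kept, so these counts are no balanced check. Fits on 2 groups gave 295 and 0 for the first pair, 1 for double-mutant against Hnf4g-removed and 1 for Hnf4a-removed against Hnf4g-removed. With a minimum count of 50 Hnf4g removal had 32, double-mutant against Hnf4g-removed 16, Hnf4a-removed against Hnf4g-removed 24 and the interaction with subset 23. Voom gave 11, 34, 39 and 6 for Hnf4g removal and the next 3 comparisons. Thinning gave 28 for Hnf4g removal and 7 for double-mutant against Hnf4g-removed, which had 13 with RLE factors. The comparisons of the wild-type gates and of control mTEChi with mTEClo stayed within 1.5 times of their counts under all these alternatives.

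Leaving out each library gave 47 to 207, 0 to 1, 9 to 23, 7 to 53, 1 to 119, 2 to 39, 0 to 8, 71 to 188 and 1 to 157 genes in the same order. The signature's mean ranged from -0.22 to -0.029 for Hnf4a removal, passing without control replicate 1 or Hnf4a-removed replicate 3, from -0.083 to 0.097 for the interaction of the genotypes, from -0.38 to -0.22 against Hnf4a-removed, from -0.16 to -0.012 against Hnf4g-removed, from 0.11 to 0.34 for Hnf4a-removed against Hnf4g-removed and from 0.039 to 0.17 for the interaction with subset. A signature of log2 fold change over 2, or of the 200 genes of smallest p, passed for Hnf4a removal (-0.17 and -0.15) and for double-mutant against Hnf4g-removed mTEClo (-0.18 and -0.21). These passes came with the preset correlation and none of them held with an estimated one.

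By the correlation rule the replicate number was not shown to pair libraries, except on the smaller gene set for Hnf4a-removed against Hnf4g-removed mTEClo. In that comparison the block ended no call but those of Ccl6 and Rhoc. In mTEClo the leading component of the deviations still rose with the number in every genotype, so a factor shared by equal numbers stays open. As a block the number gave 7037 genes for the wild-type gates. Among the 9284 genes with a mean log2 CPM of at least 4, all 3 entero-hepato libraries correlated best with their own number. Over all 21815 genes 2 of them did, so this is a hint from the data and not the design. The block gave 204, 1 (not Serinc3), 25, 104 (47 shared), 7, 17, 0, 89 and 5 genes in the order above, and 8488 for control mTEChi against mTEClo.

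Lists that did not pass took the other direction with the block, with adjusted p: pancreatic acinar 0.768 and fibroblast 0.413 for Hnf4a removal, fibroblast 0.812 for Hnf4g removal, transcription factors 0.986, keratinocyte 0.313 and endothelium 0.972 against Hnf4a-removed, transcription factors 0.950 and thymocyte 0.899 against Hnf4g-removed, transporters 0.993 and transcription factors 0.987 for Hnf4a-removed against Hnf4g-removed, lipid handling 0.557, plasma proteins 0.788, xenobiotic metabolism 0.619, neuroendocrine 0.517 and myeloid 0.459 for the interaction of the genotypes, and acinar 0.899 for that with subset. With fry transporters and transcription factors for Hnf4a-removed against Hnf4g-removed (0.991 each) and brush border for the interaction with subset (0.960) did so. Of 290 list tests with the preset correlation, an estimated one ended 74 passes, fry ended 41 and added 17, and the block ended 2 and added 18, all without a change of direction.

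Among 302 tests of named genes DESeq2 ended 1 call and added 3, voom ended 37 and added 2, the block ended 24, thinning 4 and RLE factors 2, and leaving out the 3 libraries ended 16 and added 6. Aire passed without the 3 libraries in double-mutant mTEClo against control (log2 fold change -1.29), Hnf4a-removed (-1.21) and Hnf4g-removed (-1.82) and for the interaction of the genotypes (-1.74), and against Hnf4g-removed also without Hnf4g-removed replicate 1 (-1.82). For the interaction with subset Aire passed with DESeq2 (1.20) and without control mTEClo replicate 1 (1.44). The 3 libraries had the lowest Aire of their groups (control 207, Hnf4a-removed 188 and Hnf4g-removed 166 CPM of the plain totals). Double-mutant replicate 1, at 182 CPM, was kept. Leaving them out raises Aire in the comparison groups alone, so passes without them are no separate evidence of lower Aire in double-mutant mTEClo. Hnf4g passed in double-mutant mTEClo without the 3 libraries (-1.41) and between control subsets with voom (0.67).

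Other values of Hnf4a, Hnf4g and Aire, none of them called, changed sign. Hnf4a was at 0.068 against Hnf4a-removed and -0.14 for Hnf4a-removed against Hnf4g-removed when thinned, and -0.00062 in the latter with voom. It was at 0.029 between control subsets with RLE factors and with DESeq2. For the interaction of the genotypes Hnf4a was at -0.050 and Hnf4g at -0.25 with the block, and Hnf4g at -0.0083 with voom. Hnf4g was at 0.023 for the interaction with subset without control mTEClo replicate 1. Leaving out each library gave Aire -0.40 to 0.14 for Hnf4a removal; Hnf4a -0.29 to 0.18, -0.29 to 0.063, -0.27 to 0.19, -0.51 to 0.24 and -0.39 to 0.31 for double-mutant against Hnf4a-removed, against Hnf4g-removed, Hnf4a-removed against Hnf4g-removed, mTEChi and between control subsets; and Hnf4g -0.22 to 0.079 for Hnf4a-removed against Hnf4g-removed, -0.26 to 0.23 for the interaction of the genotypes and -0.49 to 0.21 for that with subset.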

Other observations

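The ribosomal protein test was chosen only after the values were seen. The genes lower in the entero-hepato gate than outside it, a set fixed by the same rule as the signature, were higher in double-mutant than in control mTEChi. Over 2147 measured genes the mean log2 fold change was 0.21, 27.5% of them were negative, and camera gave p = 7.74e-09 with the preset and 0.0051 with an estimated correlation, while edgeR called 2 of them higher and 1 lower. In double-mutant mTEClo the set did not pass (mean -0.12, direction up in camera, down in fry; camera p = 0.87, and 0.85 with an estimated correlation). The difference between the subsets passed with both correlations (mean 0.33 over 2225 genes, p = 4.3e-06 and 0.000753).

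Ribosomal protein genes took 1.36% of the counts in double-mutant mTEClo (SD 0.0343, n = 4) against 1.56% (SD 0.0471, n = 4) in control mTEClo, with p = 0.0286 by a two-sided exact permutation test, the smallest that the 70 splits allow. The share was 1.63% (SD 0.120, n = 3) in Hnf4a-removed and 1.74% (SD 0.145, n = 3) in Hnf4g-removed mTEClo, and control mTEClo replicate 1, at 1.49%, stood apart from its group in this measure. In mTEChi the share was 2.31% (SD 0.442) in double-mutant against 1.66% (SD 0.116) in control cells, with exact p = 0.0571. In the wild-type gates it was 0.940% (SD 0.107, n = 3) in the entero-hepato gate and 2.33% (SD 0.0632, n = 3) outside it.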
